A study of Homo sapiens with 11 samples.

How the data were processed

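RNA was measured by stranded poly(A) RNA-seq in 3 control and 3 mutant cortical organoid samples, accessible chromatin by ATAC-seq in hESC (H1, control and mutant, 1 library each), and DEAF1 binding by ChIP-seq in H1 cells (1 DEAF1 and 1 input library), per the labels. Groups and replicate numbers came from the sample titles. The titles give day 70 for the organoids and the design text day 75.

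The deposited RNA table holds TPM per transcript model. The submitters' processing notes name fastp 0.20.1, FastQC 0.11.9, STAR 2.7.9a, SAMtools 1.10 and Salmon 1.5.2 and the build GRCh38, without their roles or order; the annotation release is not given in the sources used here. Each TPM column summed to 1000000 over 254129 rows, so depth is not kept in these values. Rows without a gene symbol made up 29.4% of the rows and held 26.4 to 27.6% of the TPM, and stayed out of the gene tests. The rows of each symbol were summed to 51468 symbols. Of these, 30556 matched a current gene symbol of the RefSeq table (assembly GRCh38.p14), 1834 matched through a synonym and 19078 did not match. Summing over transcript models counts a gene once, but reads shared between close paralogs, pseudogenes or overlapping genes could be split between them, so levels of histone and other multigene families are uncertain.

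The deposited ATAC signal columns were taken as read counts per 401 bp peak divided by a size factor per library. This was inferred from the values, since the column names give only the library. All values were whole multiples of 1 step per column within 0.01 (100% of values). That step was taken as 1 read, and its inverse as the library size factor. The authors' RPM columns are scaled to the reads in the listed peaks, not to all mapped reads, and the authors' letter per peak follows a difference of 1 in log2(RPM + 1). The deposited ChIP signal column for DEAF1 was likewise taken as a read count per region over a size factor (100% of values whole within 0.01). The submitters' processing notes name Trimmomatic, BWA, Picard, MACS2, DiffBind, HOMER, ChIPseeker and deepTools; how the regions were called is not given in the sources used here. In the ChIP table, 2 value columns matched no sample of the series and were not used, and no column for the input library or for H1 ATAC was used. The table labelled for H1 equals the ATAC table in its 19 columns and was not used separately. The ATAC column named after DEAF1 was taken as the mutant library, since the other is named as the control. Coordinates are those of the deposited tables on GRCh38, and gene positions are from the RefSeq table. Peaks on the Y chromosome, Y-linked genes, XIST and TSIX were left out, leaving 31868 of 31911 ATAC peaks and 1239 of 1242 ChIP regions.

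Genes with TPM of at least 1 in at least 3 libraries (13068) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, no covariates, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. For 39 gene lists fixed before the data were examined, those with at least 5 tested genes (31) were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Lists overlap in part, so they are not independent. Genes with a ChIP region or a changed ATAC peak at the promoter (within 3 kb of a transcription start) were tested with camera and with two-sided Fisher's exact tests per direction, among tested genes with a RefSeq match. Random placements (1000) and random sets (10000) gave chance levels for overlaps and for ATAC medians. Shares have Wilson 95% intervals and ratios of reads exact binomial ones; both cover counting error only, since reads are not independent molecules. Peak work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and TMM factors used edgeR 4.0.16.

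Genes named in the report were chosen by a rule set before the data were examined: DEAF1, the 12 largest rises and 12 largest falls among named genes past the threshold with a mean of at least 5 TPM in the higher group and no overlap between groups, up to 4 members of each list with the lowest p, 3 genes from earlier work, the 8 strongest ChIP regions, up to 8 changed genes with a promoter region, and the 5 strongest ATAC peaks per direction. The genes with promoter peaks named under the other observations were chosen after their values were seen. The scripts were tested on simulated data. For mutant against control organoids, in a simulation with 12819 genes tested, limma recovered 30 of 100 genes changed by 1 on the log2 scale and 94 of 100 changed by 2, and called 10 of 12619 unchanged genes. Changes were placed only in genes that were not low, and noise was drawn separately for each gene. Recovery of low genes, and calls under a profile shared by libraries, were therefore not simulated. In a simulation of the ATAC comparison with 31868 peaks, the exact binomial test recovered 81.0% of 200 peaks changed 4-fold, and 1.82% of its calls were false. The real comparison has 1 library per condition, so the spread between libraries is unknown. That share is therefore not an error rate for the real ATAC calls. Alternatives covered the pseudocount, the filter on low values, TMM and quantile scaling, the replicate block, array weights, each library left out, variance settings of limma, the test per transcript, the promoter distance, the overlap and stricter thresholds. The alternatives added after seeing the data were library size, loess and binomial tests for ATAC, a minimum of 20 reads and a low-read group for ChIP regions, and the RNA fits without control 2 and mutant 3 or with a covariate for both.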

Results

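The series measured how a mutation of DEAF1, a transcription factor that binds DNA through its SAND domain, changes cortical organoids and human embryonic stem cells (hESC). Cortical organoids are 3-dimensional cultures of stem cells patterned toward the cerebral cortex. RNA-seq was made from 3 control and 3 mutant organoid samples, whose titles give day 70 and whose design text gives day 75. ATAC-seq, which cuts accessible DNA with a transposase, was made from hESC with 1 control and 1 mutant library, and 1 library of the hESC line H1. ChIP-seq of DEAF1 was made from H1 cells, with 1 DEAF1 and 1 input library. The labels do not say whether the organoid samples of a group came from separate cultures, so p-values measure the spread between these samples only. The RNA values were TPM, a length-scaled share of all transcripts, so the depth of these libraries is unknown. The control and mutant ATAC libraries held 2949464 and 1272727 reads in 31911 listed peaks, and the DEAF1 ChIP library held 11873 reads in 1242 listed regions.

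The mutated gene itself did not separate the groups in the organoid RNA. DEAF1 was at 7.72 ± 3.31 TPM (SD, n = 3) in controls and 5.40 ± 1.05 TPM (SD, n = 3) in mutants, with single libraries at 11.5, 6.15 and 5.48 TPM in controls and 4.30, 5.52 and 6.39 TPM in mutants. The log2 fold change of DEAF1 was -0.40 ± 0.30 (SE), with a limma adjusted p of 0.514. A mutation that leaves the transcript in place would not show in these values, and the labels do not name the mutation. EIF4G3, a translation initiation factor tied to DEAF1 in earlier work, was at 44.7 ± 16.9 TPM in controls and 50.9 ± 15.3 TPM in mutants (SD, n = 3 each; limma adjusted p = 0.796). HNRNPA2B1, an RNA-binding protein gene, was at 1065 ± 154 TPM in controls and 1436 ± 97.8 TPM in mutants (limma adjusted p = 0.162). HTR1A, a serotonin receptor gene, was at 0.473 TPM or less in each of the 6 libraries and was not tested. The fixed list of DEAF1 targets and partners from earlier work had 9 tested genes, of which 0 passed the limma test; 0 passed when adjusted over the list alone, and the lowest unadjusted p was 0.0293, for HNRNPA2B1. Its camera adjusted p was 0.575.

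The comparison of mutant with control organoids asks which genes differ at this age. Among the genes past the threshold, the excitatory neuron genes NEUROD2, NEUROD6 and SLC17A7 were lower in the mutant organoids, and WNT8B, OTX2 and PMEL were higher. Of 31 fixed gene lists 17 passed camera with a preset correlation and 0 with an estimated correlation. Of 13068 genes tested with limma on log2(TPM + 1), 531 were higher and 486 were lower in mutants at an adjusted p under 0.05. Of these, 391 were higher and 396 were lower by at least 2-fold on that scale. The groups did not overlap for 3650 genes, or 27.9% of those tested, where chance gives 10%. The count depended on single libraries: it was 455 without control 1, 1081 without control 2, 487 without control 3, 282 without mutant 1, 195 without mutant 2 and 510 without mutant 3. Control 2 and mutant 3 stood apart from the other libraries on the second principal component, which held 35.8% of the variance, and without both of them 1182 genes passed, 675 of them shared with the 1017.

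The largest rises were led by PMEL, a melanosome structural gene on chromosome 12 (55954105 to 55966709, GRCh38), which went from 1.11 ± 0.593 to 84.9 ± 10.5 TPM (SD, n = 3 each). CRABP2, a retinoic acid binding protein, rose from 7.75 ± 2.11 to 88.8 ± 17.9 TPM, and HMGA2, a chromatin protein of early progenitors, from 3.85 ± 1.65 to 46.1 ± 23.5 TPM. The midline signalling gene WNT8B rose from 0.156 ± 0.0295 to 10.8 ± 7.90 TPM, the transcription factor LHX9 from 1.33 ± 0.307 to 20.01 ± 8.11 TPM, and OTX2, a transcription factor of the rostral brain and choroid plexus, from 35.1 ± 10.4 to 226 ± 47.0 TPM. PLS3, COL9A2, OLFM3 and EBF1 rose by between 2.67 and 2.94 on the log2 scale. CALB1 and RSPO2, a Wnt agonist, rose by 3.08 and 2.87, but both lost the call when control 1, mutant 1 or mutant 2 was left out. The highest limma adjusted p of these 12 genes was 0.0177.

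The largest falls were led by SLA, an adaptor protein gene on chromosome 8 (133036728 to 133102602, GRCh38), which went from 132 ± 51.7 to 0.385 ± 0.143 TPM (SD, n = 3 each). The transcription factors NEUROD6 and NEUROD2, which mark excitatory cortical neurons, fell from 116 ± 41.3 to 2.17 ± 0.273 TPM and from 34.8 ± 8.46 to 0.243 ± 0.0348 TPM. LMO3, a transcription cofactor gene, fell from 1759 ± 182 to 58.1 ± 17.5 TPM. MEF2C, a neuronal transcription factor, fell from 144 ± 103 to 3.58 ± 1.06 TPM, and NFIB, a transcription factor of late cortical development, from 177 ± 65.0 to 8.38 ± 2.44 TPM. The astrocyte filament gene GFAP went from 166 ± 209 to 1.54 ± 0.268 TPM, with single controls between 32.1 and 406 TPM. LMO7, BCAN, SEZ6 and PDE1A changed by between -4.79 and -4.28 on the log2 scale. AQP4, an astrocyte water channel, changed by -4.35 and lost the call when control 1, mutant 1, mutant 2 or mutant 3 was left out. The highest limma adjusted p of these 12 genes was 0.0327.

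**Figure D1:**
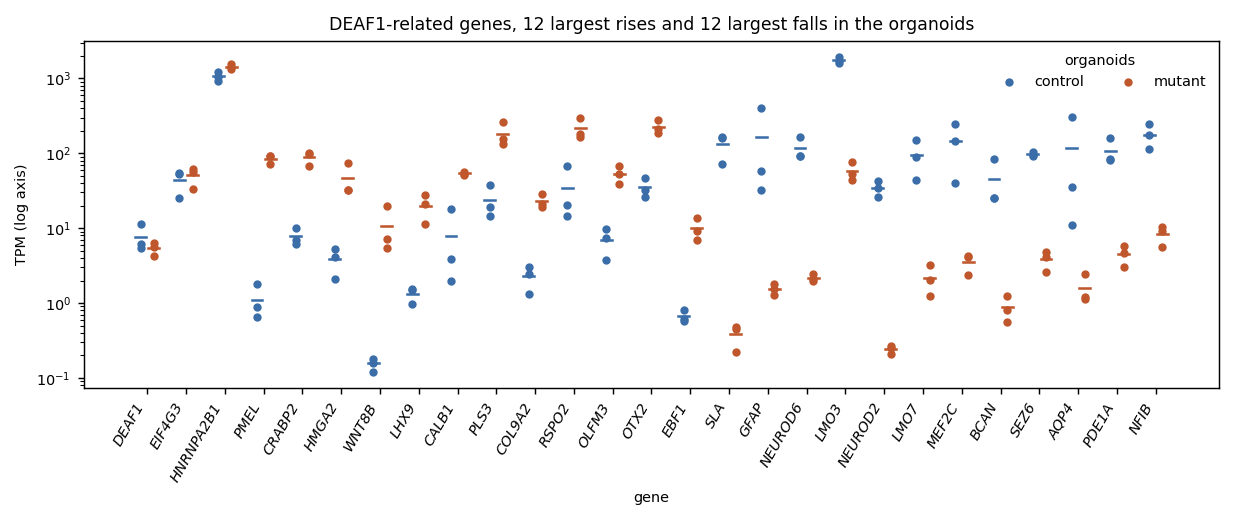
TPM on a log axis for 27 genes in the 3 control and 3 mutant organoid libraries; points are libraries and bars are group means. The DEAF1 groups overlap between 5.48 and 6.39 TPM, whereas all 3 mutants lie above the controls for PMEL and below them for NEUROD6.

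In 5 fixed lists of neuron and synapse genes, more of the genes past the threshold fell than rose, and most members did not pass in 4 of them. Of 12 tested deep-layer neuron genes, 6 fell and 1 rose (10 and 1 adjusted over the list alone), with a median log2 fold change of -2.001 and a camera adjusted p of 2.75e-07. BCL11B, a deep-layer transcription factor, fell from 18.3 ± 7.91 to 1.59 ± 0.190 TPM (SD, n = 3 each), and HS3ST4 and GRIK3 fell by 2.08 and 2.87 on the log2 scale. The member that rose was FOXP2, a transcription factor of corticothalamic neurons, by 2.25 on the log2 scale, named here because it went against the list; its call was lost without control 1 or control 3. Of 10 upper-layer genes, 3 fell, among them PLXND1, a semaphorin receptor, from 19.4 ± 2.52 to 1.35 ± 0.212 TPM; 4 passed adjusted over the list alone. The upper-layer median was -0.66 with a camera adjusted p of 0.0310, which was lost when control 3 or mutant 3 was left out. Of 17 pan-neuronal genes, 4 fell, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.00e-05). The synaptic gene SNAP25 fell from 153 ± 10.3 to 45.2 ± 0.708 TPM. The others past the threshold were NEUROD2 and NEUROD6, named above as markers of excitatory cortical neurons, and MAPT. The call of MAPT was lost in at least 1 fit without 1 library. Of 21 glutamatergic synapse genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 5.26e-05). The vesicular glutamate transporter SLC17A7 fell from 48.2 ± 4.64 to 2.15 ± 0.906 TPM, whereas SLC17A6, the transporter used mostly outside the cortex, rose from 1.36 ± 0.172 to 10.0 ± 2.38 TPM. Of 16 presynaptic vesicle genes, 3 fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00214). With an estimated correlation the adjusted p of these 5 lists lay between 0.271 and 0.568, so their calls rest on the preset correlation.

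Most tested genes of the cortical hem, the midline signalling centre, and choroid plexus, the secretory epithelium next to it, rose past the threshold. Of 19 tested genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 1.48 and a camera adjusted p of 2.34e-11. RSPO1, another Wnt agonist, rose from 0.358 ± 0.0852 to 5.91 ± 1.79 TPM and LMX1A, a roof plate transcription factor, from 5.04 ± 1.54 to 20.9 ± 1.76 TPM (SD, n = 3 each). Of 9 genes of Cajal-Retzius cells, early neurons born at the hem, 7 rose (8 rose and 1 fell adjusted over the list alone; median 1.56, camera adjusted p = 1.18e-07). Their secreted product RELN rose from 4.94 ± 1.86 to 29.4 ± 6.06 TPM, and BARHL2 from 0.119 ± 0.0674 to 2.40 ± 0.448 TPM. Of 15 Wnt pathway genes, 7 rose (11 rose and 2 fell adjusted over the list alone; camera adjusted p = 5.82e-05), among them the Wnt target APCDD1 from 19.2 ± 9.33 to 98.6 ± 18 TPM and WNT5A from 3.44 ± 0.613 to 16.7 ± 6.33 TPM. Of 7 retina and pigment epithelium genes, 4 rose (4 adjusted over the list alone; camera adjusted p = 0.000248), among them MITF, the master regulator of pigment cells, from 2.33 ± 0.859 to 13.3 ± 2.45 TPM. With an estimated correlation the adjusted p was 0.112 for the hem and for the Cajal-Retzius list, 0.262 for the Wnt list and 0.140 for the retina list.

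Glial and progenitor genes moved in both directions. Of 14 astrocyte genes, 6 fell (10 fell and 1 rose adjusted over the list alone; median -1.56, camera adjusted p = 2.74e-06, and 0.292 with an estimated correlation). ALDOC, a glycolytic enzyme of astrocytes, fell from 99.5 ± 45.5 to 18.4 ± 1.83 TPM (SD, n = 3 each), a call that was lost without mutant 2. Of 18 radial glia genes, 5 fell and 3 rose (5 and 6 adjusted over the list alone; camera adjusted p = 0.701): HOPX, a marker of outer radial glia, fell from 405 ± 119 to 21.6 ± 7.21 TPM, FABP7 from 615 ± 151 to 98.3 ± 11.1 TPM, and PROM1 rose from 10.7 ± 1.99 to 39.5 ± 8.52 TPM. Of 20 cell cycle genes, 9 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.89, camera adjusted p = 2.35e-11, and 0.244 with an estimated correlation), among them CCNB1, a mitotic cyclin, from 24.9 ± 1.59 to 67.5 ± 8.67 TPM, which lost its call without mutant 2. Of 11 intermediate progenitor genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.165), and EOMES, their transcription factor, went from 21.4 ± 4.00 to 8.496 ± 1.89 TPM, a call lost in 5 of the 6 fits that left out 1 library. Of 13 dorsal forebrain identity genes, 6 rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.105, past the threshold without control 1, control 2 or control 3). DMRT3, a factor of the medial cortex, rose from 0.507 ± 0.191 to 4.34 ± 1.53 TPM.

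**Figure D2:**
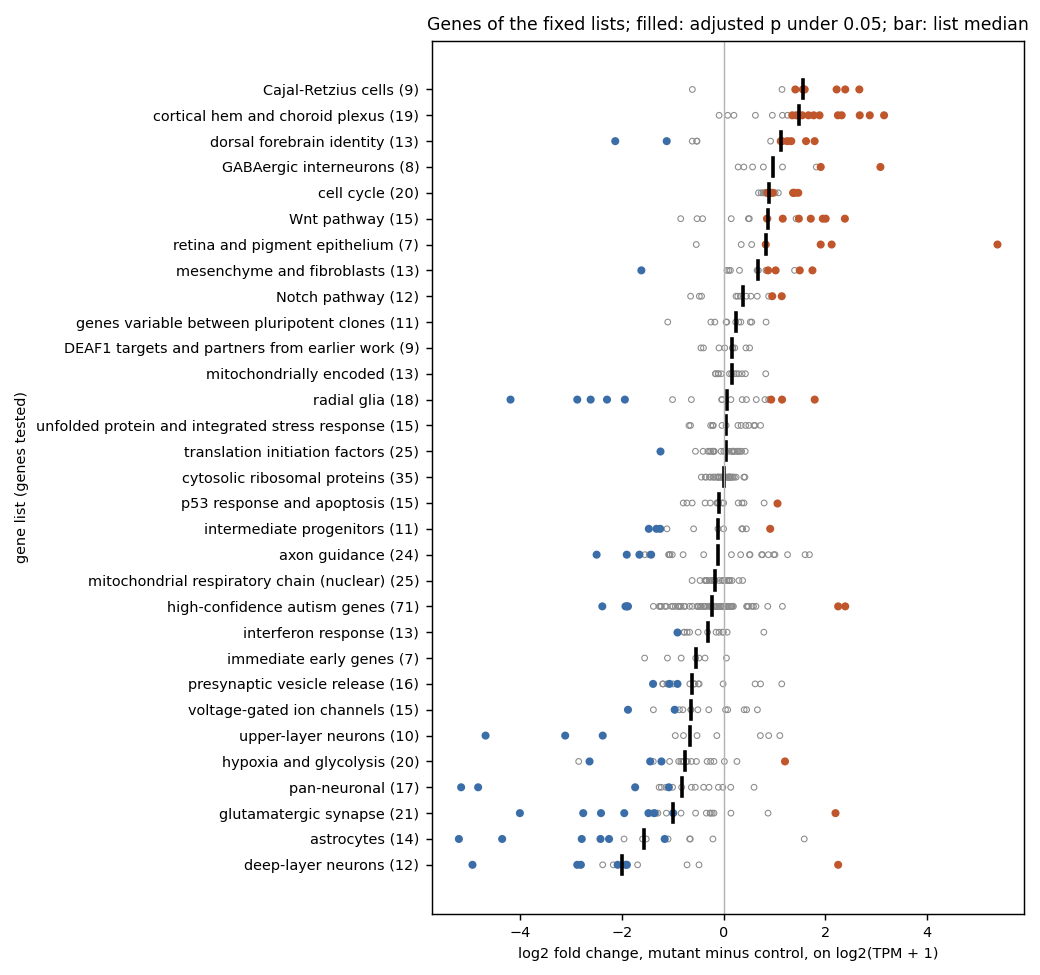
Log2 fold change (mutant minus control, on log2(TPM + 1)) of each tested gene of 31 fixed lists, ordered by list median; filled points passed limma at an adjusted p under 0.05 and black bars are list medians. The medians run from -2.001 for deep-layer neuron genes to 1.56 for Cajal-Retzius genes.

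Further lists passed camera with the preset correlation. Of 8 GABAergic interneuron genes, 2 rose (4 adjusted over the list alone; camera adjusted p = 0.000104), DLX1 from 0.0932 ± 0.0434 to 3.19 ± 1.12 TPM (SD, n = 3 each) and CALB1. Of 13 mesenchyme genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.000651), POSTN from 0.849 ± 0.210 to 4.22 ± 0.632 TPM among those that rose and THY1, also a neuronal surface gene, from 38.4 ± 9.09 to 11.7 ± 1.68 TPM. Of 20 hypoxia and glycolysis genes, 3 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 2.21e-05), with NDRG1 falling from 100 ± 5.83 to 15.5 ± 3.15 TPM and the glucose transporter SLC2A1 rising from 8.40 ± 2.64 to 20.1 ± 0.707 TPM, a call lost in 4 of the 6 fits that left out 1 library. Of 71 high-confidence autism genes, 4 fell and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.0401), BCL11A from 66.7 ± 11.0 to 11.97 ± 1.89 TPM and TBR1, whose call was lost without mutant 1, among the falls, and RELN and FOXP2 among the rises. Of 15 voltage-gated ion channel genes, 2 fell (4 adjusted over the list alone; camera adjusted p = 0.0411), and of 12 Notch pathway genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0345). The camera calls of the autism, ion channel and Notch lists were each lost without control 1, control 3 or mutant 3, that of the Notch list also without mutant 2. The calls of these 3 lists and of the mesenchyme list were lost with a minimum of 5 TPM, where the GABAergic list kept too few genes to be tested. With an estimated correlation the adjusted p of these 6 lists lay between 0.140 and 0.862.

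Housekeeping lists did not pass with all libraries: the camera adjusted p was 0.764 for 35 cytosolic ribosomal proteins, 0.719 for 25 translation initiation factors, 0.381 for 25 nuclear-encoded respiratory chain genes and 0.381 for 13 mitochondrially encoded genes. It was 0.381 for the unfolded protein response, 0.911 for the p53 response, 0.575 for axon guidance (24 genes, of which 4 fell, among them PLXNA2 and EPHA5, and 7 rose and 6 fell adjusted over the list alone; PLXNA2 and EPHA5 each lost the call in at least 1 fit without 1 library), 0.154 for immediate early genes, 0.0650 for the interferon response and 0.403 for genes variable between pluripotent clones. Several of these lists passed when 1 library was left out: the ribosomal list with a median of 0.16 without control 2 and of -0.16 without mutant 3, the respiratory chain list without control 1, control 3 or mutant 3, and the mitochondrially encoded list without mutant 3. The immediate early and interferon lists passed without control 1 or mutant 3. For 8 lists fewer than 5 genes could be tested: oligodendrocyte lineage (4 of 13 genes), diencephalon to hindbrain (3 of 26), skeletal muscle (1 of 12), epithelium (3 of 12), endothelium (2 of 10), microglia (2 of 12), pluripotency (1 of 11) and replication-dependent histones (3 of 18).

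The DEAF1 ChIP-seq asks where the protein binds in H1 cells. Of the 8 listed regions with the most reads, 7 lay at promoters, 2 of them of histone genes. The region with the most reads was at the promoter of C6orf52 (chromosome 6, 10694605 to 10695005, GRCh38), with 234 reads (exact 95% Poisson interval 205 to 266, which covers counting error only). It was followed by the promoters of the histone genes H4C3 (136 reads; chromosome 6, 26103735 to 26104135) and H3C12 (108 reads; chromosome 6, 27890636 to 27891036). Next came an intergenic region with 89 reads (chromosome 1, 125180003 to 125180403), whose nearest gene, EMBP1, started 3660658 bp away. Its ATAC signal, 253.9 RPM in the control and 170.5 RPM in the mutant library, was the highest of the 8. How uniquely its reads map was not tested. The promoters of DHX33-DT (78 reads; chromosome 17, 5468896 to 5469296), SCGB2B2 (74 reads; chromosome 19, 34677072 to 34677472), MARS1, a tRNA synthetase gene (72 reads; chromosome 12, 57487773 to 57488173), and IFT140, a cilium gene (72 reads; chromosome 16, 1611607 to 1612007), completed the first 8. None of the listed regions had DEAF1, EIF4G3, HNRNPA2B1 or HTR1A as its nearest gene.

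Most listed regions held few reads. The median was 8 reads, and 191 of the 1239 regions analysed had 5 reads or fewer. Promoters held 149 regions, or 12.03% (Wilson 95% interval 10.33 to 13.96%), introns 45.7% and distal intergenic sequence 38.8%. Among the 30 regions with at least 20 reads, a minimum chosen after the data were seen, 23 lay at promoters (76.7%, interval 59.1 to 88.2%). For comparison, 55.4% of the ATAC peaks lay at promoters. The values analysed hold no input column, so no enrichment over input was computed.

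The overlap with open chromatin was taken against the ATAC peak list that the H1 table shares with the control and mutant hESC, since the 19 columns of the H1 table equalled those of the other in each cell. Of the 1239 regions, 31 overlapped an ATAC peak by at least 1 bp (2.50%, Wilson 95% interval 1.77 to 3.53%), against a mean of 10.4 and a maximum of 23 in 1000 random placements on the same chromosomes. Of the 30 regions with at least 20 reads, 17 overlapped an ATAC peak (56.7%, interval 39.2 to 72.6%), and the promoter regions of C6orf52, H4C3, H3C12 and MARS1 were among them. Among the regions below the median in reads the overlap was 3 of 486, where the random mean was 4.00. The random placements were drawn evenly along each chromosome and were not matched on promoter location. An excess over them therefore does not separate DEAF1 binding from promoter location.

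Genes with a DEAF1 region at the promoter were then looked up in the organoid RNA. Of 72 such genes tested, 3 rose and 3 fell, against 2.98 and 2.72 expected. TMEM108, a neuronal membrane protein gene, fell from 26.5 ± 8.04 to 4.04 ± 1.22 TPM (SD, n = 3 each), ARPP21, a gene of cortical and striatal neurons, from 51.3 ± 35.3 to 2.94 ± 1.52 TPM, and NBEA, a vesicle traffic gene, from 77.3 ± 31.6 to 26.2 ± 4.56 TPM. PERP rose from 1.34 ± 0.2 to 5.56 ± 1.32 TPM, FYB2 from 0.773 ± 0.357 to 3.27 ± 0.348 TPM and STK33 from 23.0 ± 6.98 to 52.8 ± 1.83 TPM. The odds ratio was 1.01 (95% interval 0.202 to 3.09) for rises and 1.11 (0.222 to 3.40) for falls, with two-sided Fisher's exact p of 1 and 0.753 (0.994 for falls adjusted over 6 tests). The median log2 fold change of the set was 0.08 (limma camera adjusted p = 0.476 over 3 sets). When every gene nearest to any listed region was taken, the odds ratio was 1.71 for rises (27 genes, Fisher's exact p adjusted over 24 tests 0.0432) and 2.30 for falls (32 genes, 0.000361). That set did not move one way as a whole (limma camera unadjusted p = 0.388). Most listed regions lay outside promoters and held few reads, and the genes were not matched on length. The excess therefore cannot be tied to DEAF1 binding.

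The ATAC comparison of mutant with control hESC had 1 library per condition, so differences have no replicate check. The authors' deposited letters marked more peaks higher than lower: 5814 peaks were marked higher in the mutant library and 1911 lower, by a difference of at least 1 in log2(RPM + 1), with RPM scaled to the reads in the listed peaks. That split of 75.3% higher depended on the scaling: with library size factors 3761 peaks were higher and 3898 lower (49.1% higher). Peaks outside promoters made up most of those marked higher, of which 34.3% lay at promoters, against 45.8% of those marked lower and 61.3% of the rest. The median difference was 0.51 in the weakest of 5 groups of peaks by mean signal and -0.26 in the strongest. The control library had 1.25 times as many reads in peaks per unit of library size as the mutant library.

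**Figure D3:**
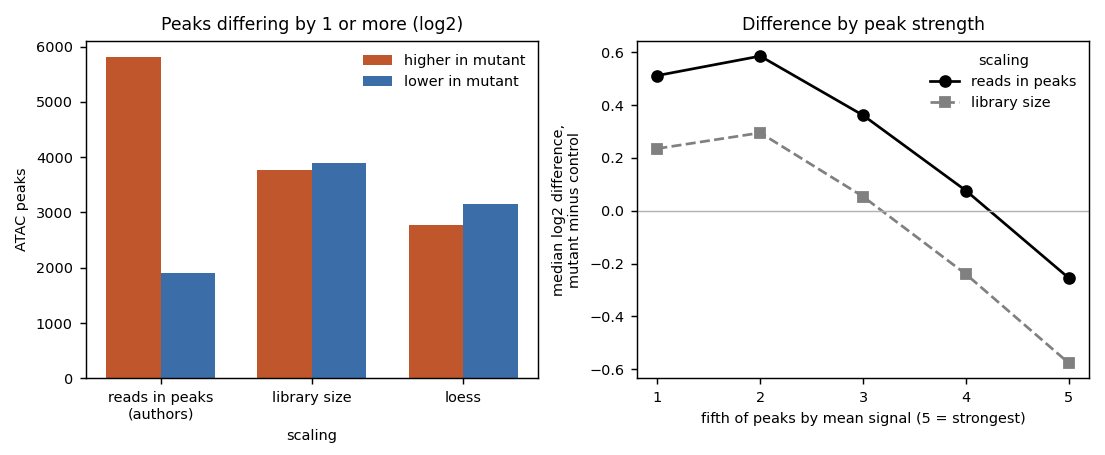
Left, number of ATAC peaks that differed by at least 1 on the log2 scale between the mutant and the control hESC library under 3 scalings; right, median log2 difference in 5 groups of peaks by mean signal. Higher peaks outnumber lower ones, 5814 to 1911, with reads in peaks but not with library size, 3761 to 3898.

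The DEAF1 promoter itself was among the peaks with a large difference. That peak (chromosome 11, 695211 to 695611, GRCh38) had 39 reads in the control and 100 reads in the mutant library, which is 5.94-fold higher in the mutant by reads in peaks and 4.75-fold higher by library size (exact 95% interval 3.25 to 7.07, counting error only). Of 17664 promoter peaks, 69 had a difference as large. The EIF4G3 promoter peak (chromosome 1, 21176691 to 21177091) was 2.76-fold higher by reads in peaks and 2.21-fold by library size (1.504 to 3.26), whereas the HNRNPA2B1 promoter peak was 0.974-fold and 0.779-fold (0.563 to 1.07). The strongest differences lay outside promoters with 1 exception. The 5 strongest higher peaks included an intergenic peak nearest to SNTB1 on chromosome 8 (121155463 to 121155863; 11 against 90 reads, 15.2-fold by library size, 8.08 to 31.5) and an intronic peak nearest to UST-AS2 on chromosome 6 (149014635 to 149015035; 17 against 126 reads, 13.7-fold, 8.25 to 24.3), and the nearest genes of the other 3 were LOC105375972, LINC01701 and LOC105375473. The 5 strongest lower peaks included a peak nearest to GACAT3 on chromosome 2 (16185506 to 16185906) with 100 reads in the control and 0 in the mutant library, and the promoter peak of PDIA5 on chromosome 3 (123091005 to 123091405) with 183 and 3 reads; the nearest genes of the other 3 were LOC105370802, SRGAP3-AS4 and LOC105379127.

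At the 31 ATAC peaks that overlapped a DEAF1 region, the median difference was -0.19, where 10000 random sets of peaks matched on signal and promoter status had a median of 0.10 (95% range -0.19 to 0.39), a percentile of 2.77 that describes these 2 libraries. At regions at or above the median in reads the median of 28 peaks was -0.16, at a percentile of 5.96.

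Promoter accessibility in hESC was set beside the organoid RNA, which is another cell state. Of 746 tested genes with a promoter peak marked higher in the mutant library, 54 rose and 54 fell in the organoids, against 31.7 and 29.7 expected. The odds ratio was 1.88 (95% interval 1.37 to 2.53) for rises and 2.03 (1.48 to 2.74) for falls, with two-sided Fisher's exact p adjusted over 6 tests of 0.000274 and 8.503e-05. Both calls held with library size factors, where 32 and 33 of 399 genes rose and fell (odds ratios 2.05 and 2.28, adjusted p of 0.00176 and 0.000361 over 24 tests). With a difference of at least 2, which left fewer genes, both calls were lost: 5 of 79 genes rose and 6 fell, with odds ratios of 1.53 (0.480 to 3.76) and 1.996 (0.705 to 4.60) and adjusted p of 0.705 and 0.293 over 24 tests. Of 553 genes with a promoter peak marked lower, 22 rose and 19 fell, against 23.5 and 22.0 expected (adjusted p = 0.994 for both). Neither set moved one way as a whole: the median log2 fold change was -0.05 (limma camera adjusted p = 0.746 over 3 sets) for the first and 0.01 (adjusted p = 0.746) for the second. Of all peaks marked higher, 1497 lay in the weakest of 5 groups by mean signal and 139 in the strongest. The Fisher's exact tests did not match genes on peak signal or on peaks per gene, under either scaling. The excess of both rises and falls therefore cannot be tied to the accessibility change itself.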

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

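Several of the tests below were chosen after the result was seen. They covered a loss of every neuron type, scaling to reads in peaks and signal over background across all ATAC peaks. Counting error at the DEAF1 promoter was among them too. The fits for the shared library profile in the organoids and the loess fit at the DEAF1 promoter were also added after the data were seen. The other tests were written before.

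Transcript rows without a gene symbol, which no comparison above used, also differed between the organoid groups: of 22756 such rows tested with limma, 1379 passed an adjusted p under 0.05, 661 higher and 718 lower in mutants. Rows of one gene are not independent, so this is not a count of genes.

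The first pattern was a lower median of cortical projection neuron lists and a higher median of the hem and choroid plexus list in mutants. A library profile shared by control 2 and mutant 3, whose deviations from their group means correlated at 0.80 across genes, did not account for it: without both libraries the median of the deep-layer list was -2.06 and that of the hem and choroid plexus list 1.38. A few abundant genes taking the TPM did not account for it either, since TMM factors left the deep-layer median at -1.98 (-1.985 unrounded). A lower share of every neuron type would lower Cajal-Retzius genes too, yet their median was 1.56, between 1.405 and 1.62 with single libraries left out. This rests on 9 genes in bulk RNA, of cells born at the hem, whose own genes rose. The pan-neuronal list fell, with a median of -0.82. Its members with the lowest p, NEUROD2 and NEUROD6, mark excitatory cortical neurons, so this list is not independent of the projection neuron pattern. A lower share of neurons in total therefore remains open. The real grouping called 1017 genes and the highest of the other 9 splits of the 6 libraries called 0, but 10 splits are too few to reach a share under 0.05 (1 of 10 was as large). A shift of regional identity tied to the mutation may be one explanation, but a difference in patterning between organoid batches or clones remains open, because the labels give neither.

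The second pattern was the excess of ATAC peaks higher in the mutant library. With library size factors the share of higher peaks fell from 75.3% to 49.1%, so the excess may come from scaling to reads in peaks. A lower signal over background in the mutant library may also contribute, since the median difference was 0.51 in the weakest and -0.26 in the strongest of 5 groups of peaks. With 1 library per condition, an effect of the mutation cannot be separated from either and was not tested.

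The third pattern was the higher ATAC signal at the DEAF1 promoter in the mutant library. The 48 other peaks within 1 Mb were raised too, with a median of 0.68 (bootstrap 0.41 to 0.92) against 0.22 over all peaks. This stayed below 1.24, which is 50% of the change at the promoter. A uniform gain of the whole segment therefore did not account for most of that change. Whether such a gain added a smaller part cannot be told, because the other peaks were not matched on signal. A much shorter gain was not tested. Counting error did not account for the change at the promoter, as the lower bound of the ratio of reads was 3.25. A loess fit for signal over background left that change at 2.39. An effect of the mutation on its own promoter may be a hypothesis for this peak, but it rests on 1 library per condition, and a trace of the editing itself was not tested.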

How the results depend on the processing

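The ATAC scalings, the ChIP read groups, and the RNA fits on control 2 and mutant 3 were chosen after seeing the data. The 1017 changed genes (531 higher, 486 lower) became 573 (285 and 288) with a minimum of 5 TPM, where fewer genes were tested, 2962 (1501 and 1461) with array weights, 3425 (1785 and 1640) with a covariate for control 2 and mutant 3, and 1943 transcript rows (878 and 1065) of 651 genes in the test per transcript. Leaving out 1 library gave 195 to 1081 genes, of which 77 to 470 were higher and 118 to 611 lower: 455 (270 and 185) without control 1, 487 (290 and 197) without control 3, 282 (113 and 169) without mutant 1, 195 (77 and 118) without mutant 2 and 510 (254 and 256) without mutant 3. The replicate numbers did not pair the libraries (correlations of deviations of 0.43, -0.58 and -0.53 for numbers 1 to 3), and the replicate block gave 402 genes (190 and 212). Of 17 lists past the threshold, 0 passed with an estimated correlation and 13 with fry; glutamatergic synapse, presynaptic, autism and ion channel lists lost the call with fry. The set of genes with a ChIP region at the promoter and both ATAC sets stayed on the same side of the camera threshold under every alternative, whereas both Fisher's exact calls for promoter peaks higher in the mutant library held with library size (adjusted p = 0.00176 and 0.000361) and with any annotated peak (6.09e-07 and 7.29e-10) and were lost with a difference of at least 2, on 79 in place of 746 genes (0.705 and 0.293). The ribosomal protein list, at a median of 0.01, turned to -0.16 without mutant 3, and was -0.17 without control 3 and 0.16 without control 2. Promoters held 7.26% of ChIP regions within 1 kb and 76.7% with at least 20 reads, against 12.03%. The overlap with ATAC peaks, 2.50%, was 1.29% with 50% of the region covered, 3.72% for regions at or above the median in reads, 0.617% below it and 56.7% with at least 20 reads. ATAC peaks differing by 2 numbered 1153 (833 higher, 320 lower, 72.2% higher). Library size gave 3761 and 3898 (49.1%), loess 2780 and 3151 (46.9%), and the exact binomial test 4209 lower (62.1% higher) by reads in peaks and 7418 lower (35.6% higher) by library size. The median ATAC change at DEAF1 regions, -0.19, was -0.51 with library size, -0.27 with 50% covered and -0.16 at or above the median in reads. Except where stated, the cause was not tested. Of the 24 genes with the largest changes, 21 kept their call in all 6 fits without 1 library, and of 78 called list members 41 did. Unknown RNA depth limits what can be said of low genes, and 1 library per condition limits ATAC and ChIP.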

Other observations

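These 6 lists were picked after the promoter accessibility of all lists in the 2 hESC libraries was seen, with 1 library per condition. The percentiles were not adjusted for the number of lists examined. Promoter peaks of 8 epithelial genes had a median log2 difference of 2.25 in the mutant library by reads in peaks and 2.05 by library size, where random peaks matched on signal had a median of 0.33 (percentile 100). Of these, 7 were marked higher, among them ESRP1, a splicing regulator of epithelial cells (33 reads in the control and 140 in the mutant library), the adhesion gene EPCAM (29 and 89 reads), the tight junction gene CLDN3 (26 and 78 reads) and the cadherin CDH1 (14 and 41 reads). Promoter peaks of 15 radial glia genes had a median of -0.67 by reads in peaks and -1.003 by library size, at a percentile of 0.03. The glutamate transporter SLC1A3 (148 and 19 reads), FABP7 (281 and 48 reads) and PTPRZ1 (415 and 77 reads) were marked lower and TNC (98 and 100 reads) higher. The median by reads in peaks was 0.61 for 14 hem and choroid plexus genes, 5 marked higher and 1 lower (random 0.18, percentile 97.7). It was 0.82 for 6 retina and pigment epithelium genes, 1 marked higher and 0 lower (random 0.00, percentile 99.6). For 7 endothelial genes, 4 marked higher and 0 lower, it was 1.07 (random 0.42, percentile 96.5). By library size these medians were lower, at 0.31 for the hem, 0.52 for the retina and 0.80 for the endothelial list. Promoter peaks of 5 pluripotency genes had a median of 0.44 by reads in peaks, at a percentile of 66.5, and of 0.13 by library size. The list names do not identify the cells in these libraries. A difference in cell state between the 2 cultures cannot be told apart from an effect of the mutation here, and was not tested.

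Control 2 and mutant 3 differed from the other organoid libraries along the length of genes. The coefficient of a term for these 2 libraries correlated with log10 gene span at -0.58 (Spearman, 12110 genes), with a median of 0.21 in the shortest and -0.60 in the longest of 5 groups, whereas the difference between mutant and control correlated with span at 0.06.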
